A study of Penicillium oxalicum with 18 samples.

How the data were processed

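Expression was measured in 18 libraries of Penicillium oxalicum, 3 for each combination of 3 strains (wild type, hap3 deletion and hap5 deletion) and 2 carbon sources (glucose, or bran with microcrystalline cellulose). Per the labels' protocols, mycelium precultured for 24 h at 30 °C was transferred to the test medium for 24 h before RNA extraction. Those protocols describe tag libraries, in which cDNA is cut with NlaIII and MmeI next to CATG sites, whereas the deposited values are FPKM, a length-scaled unit made for reads spread along a transcript. If the libraries are tag libraries, division by length changes the levels of genes against each other. It does not change the FPKM ratio of a gene between libraries. The changes reported below are computed after a constant is added to FPKM, so division by length can alter them, mostly for low genes. It can also decide whether a low gene passes the FPKM filter. The aligner, quantifier, genome build and annotation are not given in the sources used here, nor is strand handling, so values of overlapping genes or near-identical copies are uncertain.

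The authors deposited 1 table of FPKM values with 2 decimals, per the file headers, and no read counts were used here. Columns were matched to samples by strain, medium and replicate number. The glucose columns carry the abbreviation of the sample titles, and the other medium has a different abbreviation in the table than in the titles, so it was matched by elimination, as the design has 2 carbon sources. All 18 columns were used, and 0 were left unmapped. Of the 9277 identifiers, 0 matched the reference gene table, which belongs to strain HP7-1 and lists 9964 genes, so no gene names, functions or coordinates were used. The gene lists fixed before the data were examined were not formed for that reason, and no gene list test was run.

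Depth is unknown. Low values were searched for steps that would give relative depth: for genes listed at 0 in at least 6 libraries, ratios to wild type glucose replicate 1 were gathered within 0.02 log2 units. The best ratio gathered between 6.667% and 30.0% of the low genes of a library, where whole reads would need nearly all, so relative depth was not recovered. No interval for counting error is given. An exact 0 may be a failed estimate: 213 genes were listed at 0 beside a library of at least 10 FPKM in the same group. Where a group printed for a named gene mixed 0 with higher values, library values or their limits are given in place of a mean, and no fold is given against a group at 0. No pair of libraries was identical.

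Genes with at least 1 FPKM in at least 3 libraries were tested (8681 of 9277). Values were transformed to log2(FPKM + 1), and group means over all 18 libraries were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), so that all groups shared 1 estimate of spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05 and an absolute log2 change of at least 1. The comparisons were each deletion against wild type on each medium, bran and cellulose against glucose in each strain, the interaction of each deletion with carbon source, and the hap5 against the hap3 deletion on each medium, all fixed before the data were examined. The carbon response of the hap5 against the hap3 deletion and the groups of wild type carbon responsive genes were added afterwards.

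The rule for named genes took called genes with a mean of at least 10 FPKM in a compared group and, for comparisons of 2 groups, replicates that did not overlap, ranked by log2 change. The rule asked for genes with an informative description, which was dropped as no descriptions were used, and at most 2 genes that rose and 2 that fell were named per comparison. The parts of the rule that drew on gene lists named no genes. PDE_09832, PDE_04423 and genes low, high or absent in 1 strain were chosen after their values were seen, and are named as such.

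Shared wild type libraries were allowed for by 100 simulations of unchanged groups. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, a replicate block, a fit on the compared groups only, no minimum fold and leaving out each library in turn. An alternative without genes listed at 0 in part of a group was added after the data were seen. The fit was tested on simulated data for the hap3 deletion against wild type on glucose, with 7977 genes tested and 100 genes changed by each of 2 sizes. It recovered 98% of genes changed by a log2 value of 1.5 and 99% of those changed by 3, with 2 false calls. For the interaction of the hap3 deletion with carbon source it recovered 93% and 98%, with 7 false calls. Changed genes lay between 3 and 12 on the log2(FPKM + 1) scale in wild type on glucose. Noise was normal, with the spread of the fit in every group. The figures therefore do not cover lower genes, genes listed at 0 in part of a group or groups of unequal spread. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.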

Results

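Transcript levels were measured in the filamentous fungus Penicillium oxalicum, a producer of plant cell wall degrading enzymes, in wild type strain 114-2 and in strains deleted for hap3 or hap5. Both genes encode subunits of the Hap complex, a transcription factor that binds CCAAT sequences in promoters. Mycelium was grown for 24 h on 2% glucose as preculture, then for 24 h on 2% glucose or on 1% bran with 1% microcrystalline cellulose. The 3 strains and 2 carbon sources made 6 groups of 3 libraries, 18 in all. The table listed FPKM (fragments per kilobase of gene model, scaled to the number of mapped fragments) for 9277 genes, 9241 of them with PDE locus tags and 36 with XLOC identifiers. Library totals ran from 966280 to 1202683 FPKM, and the number of genes listed at 0 from 598 to 959. The sequencing depth behind these values is unknown. The labels do not say whether the 3 replicates of a group were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Values are given as mean ± SD over 3 libraries. Changes are on the log2(FPKM + 1) scale, which understates those of low genes, and are followed by their standard error and the adjusted p of limma.

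The table pairs its identifiers with no gene names, so the deleted genes were not looked up by name. A search for genes that were at least 4 times lower in all 6 libraries of 1 strain than in each of the other 12, all of these at 2 FPKM or more, found 1 gene for each deletion strain, chosen after the values were seen. PDE_02832 lay between 8.93 and 12.18 FPKM in the hap3 deletion libraries and between 134.38 and 256.36 FPKM elsewhere. PDE_01016 lay between 1.43 and 2.22 FPKM in the hap5 deletion libraries and between 118.83 and 226.15 FPKM elsewhere. In wild type PDE_02832 was at 173.4 ± 33.8 FPKM on glucose and 151.9 ± 6.25 FPKM on bran and cellulose. PDE_01016 was at 133.5 ± 9.31 and 127.7 ± 7.43 FPKM in the same groups.

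**Figure D1:**
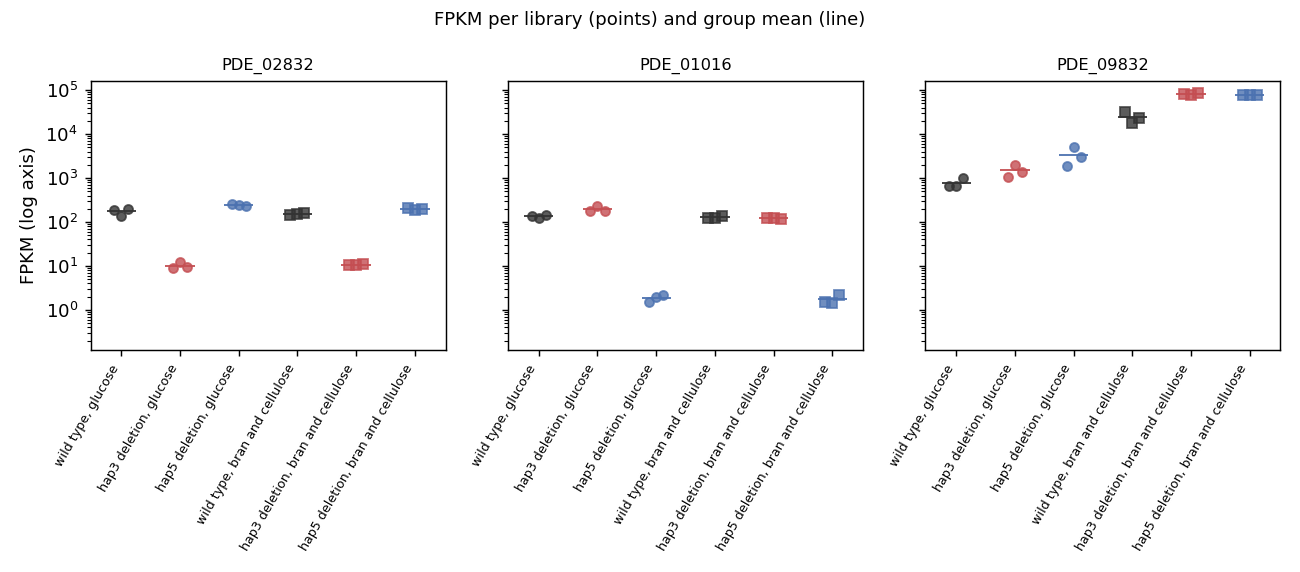
FPKM of PDE_02832, PDE_01016 and PDE_09832 in each library, on a log axis, with 3 points and a line for the mean in each of the 6 groups. PDE_02832 stayed at or below 12.18 FPKM in the hap3 deletion and PDE_01016 at or below 2.22 FPKM in the hap5 deletion, and PDE_09832 was highest on bran and cellulose in both deletion strains.

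Libraries grouped by carbon source and by the presence of a deletion. The first principal component held 49.9% of the variance and separated the carbon sources, and the second held 26.7% and separated wild type from the deletion strains. Correlations across genes between libraries of 1 group ran from 0.9526 to 0.986. Libraries of the 2 deletion strains on bran and cellulose correlated with each other at 0.9672 to 0.9813, and with wild type on the same medium at 0.7587 to 0.7906. Replicate 2 of the hap3 deletion on glucose had the highest total (1202683 FPKM) and the lowest median log2 value (4.647), and the lowest correlation within its group was 0.9526. Genes are not independent replicates, so these correlations carry no p-value.

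**Figure D2:**
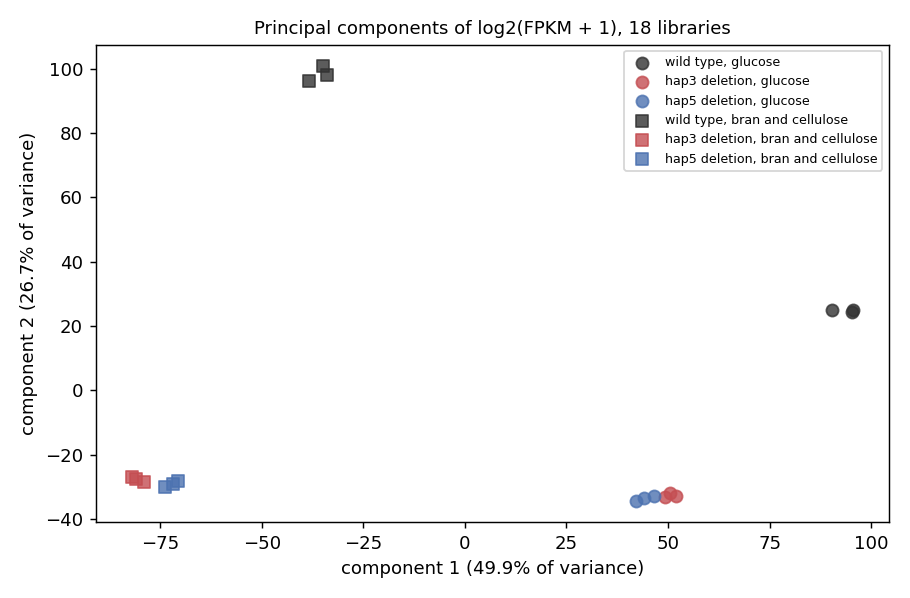
Principal components 1 and 2 of log2(FPKM + 1) for the 18 libraries, with strains by colour, glucose as circles and bran with cellulose as squares. The deletion strains lay close together within each carbon source and apart from wild type.

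The response of wild type to bran and cellulose was compared with glucose first. PDE_09315 was listed at 0 in all 3 wild type glucose libraries and stood at 9693 ± 941 FPKM on bran and cellulose. PDE_07945 rose from 0.683 ± 0.136 to 2121 ± 141 FPKM, a log2 change of 10.30 (SE 0.15, adjusted p = 6.3e-17). PDE_06955 fell from 1535 ± 599 to 0.253 ± 0.0493 FPKM, a log2 change of -10.19 (SE 0.19, adjusted p = 1.05e-15). PDE_07282 was at 1195 ± 165 FPKM on glucose and was listed at 0 in all 3 bran and cellulose libraries. PDE_09832, chosen after its values were seen as the most abundant transcript on bran and cellulose in most libraries, took 0.0686% ± 0.0176 of the FPKM total on glucose and 2.55% ± 0.734 on bran and cellulose. In all, 2017 of 8681 tested genes were higher and 1209 lower on bran and cellulose, and 523 and 238 of them changed by a log2 value of 3 or more. The excess of higher genes depended on scaling: 62.52% of calls were higher in the deposited values and 48.84% after quantile normalization. The median log2 change over all genes was 0.157, and median-of-ratios scaling moved it by -0.125.

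Deletion effects on glucose were large and ran in both directions. PDE_06126 was at 1277 ± 113 FPKM in the hap3 deletion and at 906.77, 375.61 and 576.33 FPKM in the hap5 deletion, against 4.72, 4.6 and 0 FPKM in the wild type libraries. Its log2 change was 8.65 (SE 0.78, adjusted p = 1.64e-07) in the hap3 deletion and 7.52 (SE 0.78, adjusted p = 7.28e-07) in the hap5 deletion. Without wild type replicate 3, where PDE_06126 was listed at 0, the changes were 7.815 and 6.685. PDE_09236 was listed at 0, 0 and 1.26 FPKM in wild type and at 553.03, 1657.86 and 358.33 FPKM in the hap3 deletion. In the hap5 deletion PDE_09236 was at 5.75, 32.27 and 13.82 FPKM. PDE_03484 rose from 0.253 ± 0.101 FPKM in wild type to 162.4 ± 27.1 FPKM in the hap5 deletion, a log2 change of 7.02 (SE 0.20, adjusted p = 9.25e-13). In the hap3 deletion PDE_03484 was at 212.1 ± 34.6 FPKM, a log2 change of 7.40 (SE 0.20, adjusted p = 5.81e-13). PDE_01629 fell from 1667.55, 1591.59 and 7764.53 FPKM in the wild type libraries to 1.24 ± 0.544 FPKM in the hap3 deletion and 1.3 ± 0.145 FPKM in the hap5 deletion. PDE_09166 fell from 2549 ± 193 FPKM to 3.48 ± 1.24 FPKM in the hap3 deletion and to 0.93, 7.77 and 0 FPKM in the hap5 deletion. The hap3 deletion had 1329 higher and 759 lower genes, and the hap5 deletion 1530 higher and 608 lower genes. The share of higher genes fell from 63.65% to 52.12% in the hap3 deletion after quantile normalization. In the hap5 deletion it fell from 71.56% to 60.74% after median-of-ratios scaling and to 54.22% after quantile normalization. Median-of-ratios scaling moved the median change of all genes by -0.129 in the hap3 deletion and by -0.222 in the hap5 deletion, from 0.136 and 0.236.

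On bran and cellulose the deletions lowered some of the most abundant wild type transcripts and raised others. PDE_09315, at 9693 ± 941 FPKM in wild type, was listed at 3.82, 0 and 0.37 FPKM in the hap3 deletion and at 0, 1.74 and 1.37 FPKM in the hap5 deletion. PDE_07655 stood at 769.1 ± 123 FPKM in wild type and at no more than 0.11 FPKM in any deletion library, a log2 change of -9.53 (SE 0.23) in each strain, with adjusted p values of 3.24e-14 and 3.31e-14. PDE_03634 was listed at 0 in the wild type libraries and was at 1216 ± 68.6 FPKM in the hap3 deletion and 2188 ± 332 FPKM in the hap5 deletion. PDE_02342 was listed at 0 in wild type on both media and was at 467.6 ± 13.9 and 553.6 ± 52.8 FPKM in the hap3 and hap5 deletions on bran and cellulose. PDE_09832 took 8.19% ± 0.262 of the FPKM total in the hap3 deletion and 7.68% ± 0.0621 in the hap5 deletion, against 2.55% ± 0.734 in wild type. The hap3 deletion had 1452 higher and 1160 lower genes, and the hap5 deletion 1421 higher and 1150 lower genes.

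**Figure D3:**
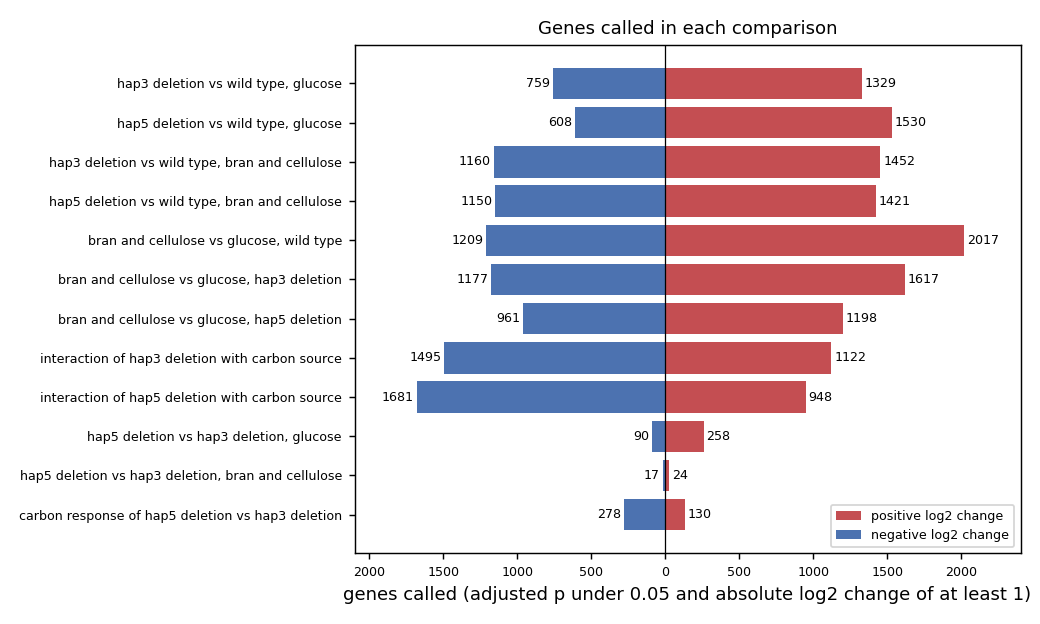
Number of genes called by limma in each of 12 comparisons, with positive log2 changes to the right of 0 and negative ones to the left. The deletion strains differed from wild type at between 2088 and 2612 genes, and from each other at 348 genes on glucose and 41 on bran and cellulose.

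Effects of the hap3 and hap5 deletions were shared to a large extent. On glucose 1130 genes were higher and 538 lower in both deletions, and 3 went in opposite directions. Independent lists of these sizes would share 234.2 higher and 53.16 lower genes. On bran and cellulose 1287 genes were higher and 1046 lower in both, with 0 in opposite directions, against 237.7 and 153.7 for independent lists. Across genes the log2 changes of the deletions correlated at 0.891 on glucose (covariance 1.31) and 0.975 on bran and cellulose (covariance 2.21). Simulated unchanged groups set against the same wild type libraries gave a correlation of 0.5 with a covariance of 0.0367 on glucose, 0.498 with 0.0369 on bran and cellulose, and a mean overlap of 0.02 genes on each medium. No simulation shared more than 1 gene, but unchanged groups give almost no calls, so this count does not measure the share of the overlap due to shared libraries. The covariances of 1.31 and 2.21, against 0.0367 and 0.0369, argue against spread between the wild type libraries as the whole source of the correlations. Part of the correlations and of the overlap may still come from these shared libraries, since 3 libraries do not divide into parts of at least 2. A difference common to all wild type libraries of a medium, other than the deletions, was not simulated and cannot be told apart.

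Carbon source responses within the deletion strains were tested in the same way. PDE_05633 was listed at 0 in the hap3 deletion on glucose and at 0.29, 0.16 and 0 FPKM in the hap5 deletion, and it reached 1028 ± 109 and 1395 ± 207 FPKM on bran and cellulose. PDE_09419 rose from 1.377 ± 0.658 to 2082 ± 158 FPKM in the hap3 deletion, with a log2 change of 9.81 (SE 0.24, adjusted p = 4.18e-14). In the hap5 deletion PDE_09419 rose from 0.92 ± 0.423 to 1938 ± 221 FPKM, with a log2 change of 9.996 (SE 0.24, adjusted p = 3.98e-14). PDE_06097 was at 332.7 ± 78 and 697.9 ± 26.8 FPKM in the hap3 and hap5 deletions on glucose and was listed at 0 in all their bran and cellulose libraries. PDE_01828 was at 317.2 ± 2.0 and 556.2 ± 98.7 FPKM in the hap3 and hap5 deletions on glucose and was listed at 0 on bran and cellulose. PDE_00326 fell from 2002 ± 438 to 2.22 ± 0.442 FPKM in the hap5 deletion, a log2 change of -9.27 (SE 0.28, adjusted p = 3.41e-13). In the hap3 deletion it fell from 389.1 ± 97 to 1.27 ± 0.418 FPKM. Wild type changed in the same direction at each of these genes. There PDE_05633 went from 0 to 597.3 ± 58.6 FPKM, and PDE_09419 from 0.52, 0 and 0.52 to 17.21 ± 5.57 FPKM. PDE_06097 and PDE_01828 went from 75.43 ± 20.5 and 225.6 ± 33.8 FPKM to 0, and PDE_00326 from 78.76 ± 29 to 5.4 ± 1.79 FPKM. The hap3 deletion had 1617 higher and 1177 lower genes on bran and cellulose, and the hap5 deletion 1198 higher and 961 lower genes. Without a minimum change the balance in the hap5 deletion turned round, with 2443 genes higher and 3009 lower, and the median log2 change over all genes was -0.073. In the hap3 deletion the share of higher genes was 57.87%, and 47.47% after quantile normalization.

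Genes called between carbon sources in wild type had a smaller median response in both deletion strains, while other genes were called only in a deletion. In the hap3 deletion 629 genes were called higher and 600 lower on bran and cellulose without the same call in wild type. In the hap5 deletion there were 407 and 487. Of the 2017 genes higher on bran and cellulose in wild type, 988 (48.98%) were also called higher in the hap3 deletion and 791 (39.22%) in the hap5 deletion, against 375.7 and 278.4 for independent lists. The median response of these genes was 1.907 in wild type, 0.993 in the hap3 deletion and 0.688 in the hap5 deletion, where the medians of all genes were 0.157, 0.046 and -0.073. The interaction test found a smaller or reversed response of 942 of them in the hap3 deletion and of 1114 in the hap5 deletion, and a larger response of 176 and 94. These interaction counts reuse the wild type libraries by which the genes were chosen. In the hap3 and hap5 deletions 115 and 96 of them were called in the opposite direction. Compared with wild type on glucose, 673 of the 2017 genes were higher and 139 lower in the hap3 deletion (median change 0.586), and 799 were higher and 116 lower in the hap5 deletion (median change 0.736). On bran and cellulose 637 were lower and 355 higher in the hap3 deletion (median change -0.298), and 673 were lower and 338 higher in the hap5 deletion (median change -0.41). Of the 1209 genes higher on glucose in wild type, 577 (47.73%) and 474 (39.21%) were called in the same direction, against 163.9 and 133.8 for independent lists, and the medians were -1.719, -0.963 and -0.776. Genes chosen on wild type replicate 1 alone, and measured in wild type replicates 2 and 3, gave median responses of 1.806, 0.996 and 0.69 for the 2138 genes higher on bran and cellulose. Their median difference from wild type was -0.246 and -0.35 on bran and cellulose and 0.52 and 0.69 on glucose in the hap3 and hap5 deletions. The 100 genes with the largest rise in wild type replicate 1, tested against wild type replicates 2 and 3, had median responses of 6.879 in wild type, 2.686 in the hap3 deletion and 2.283 in the hap5 deletion. On bran and cellulose 70 of these 100 genes were lower than in wild type and 10 higher in the hap3 deletion, and 70 were lower and 11 higher in the hap5 deletion. These groups were formed after the data were seen. All were chosen by the wild type response, so a smaller median in other strains is likely wherever responses differ between strains. Genes chosen by the response of a deletion strain were not measured in wild type, so a general weakening of the response is not shown.

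**Figure D4:**
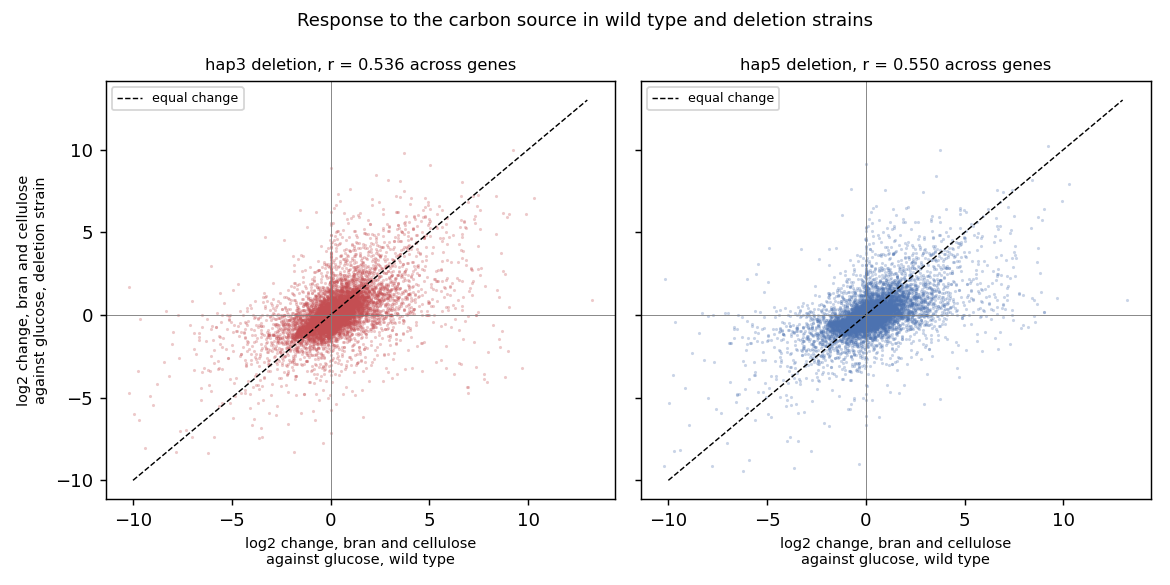
Log2 change on bran and cellulose against glucose for each of 8681 genes, with wild type on the horizontal axis and the hap3 deletion (left) or hap5 deletion (right) on the vertical axis. The correlation across genes was 0.536 for the hap3 deletion and 0.55 for the hap5 deletion, and many genes with a large wild type rise lay below the dashed line of equal change.

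Interaction between deletion and carbon source was tested gene by gene. PDE_06955 fell on bran and cellulose in wild type and stood higher there in the deletion strains, at 67.13 ± 5.25 FPKM on glucose and 223 ± 6.09 FPKM on bran and cellulose in the hap3 deletion. In the hap5 deletion PDE_06955 stood at 57.43 ± 12.6 and 263.3 ± 5.42 FPKM. Its interaction was 11.91 (SE 0.27, adjusted p = 1.06e-13) for the hap3 deletion and 12.39 (SE 0.27, adjusted p = 7.18e-14) for the hap5 deletion. PDE_09235 rose from 0.563 ± 0.448 to 1301 ± 435 FPKM in wild type, and was at 119.4 ± 98 FPKM on glucose and 12.96 ± 9.47 FPKM on bran and cellulose in the hap3 deletion, an interaction of -12.87 (SE 0.93, adjusted p = 1.7e-08). The hap3 interaction of PDE_09235 was -12.03 without hap3 deletion replicate 1 on bran and cellulose and -12.24 without replicate 2 on glucose. Its hap5 interaction was -8.65 (SE 0.93, adjusted p = 1.35e-06). PDE_04024 rose from 0.203 ± 0.131 to 196.7 ± 74.1 FPKM in wild type, and was at 4.857 ± 1.78 and 0.703 ± 0.0651 FPKM in the hap5 deletion, an interaction of -9.02 (SE 0.37, adjusted p = 3.04e-11). In the hap3 deletion PDE_04024 was at 2.817 ± 0.249 and 0.267 ± 0.248 FPKM, an interaction of -8.89 (SE 0.37, adjusted p = 3.79e-11). The hap3 interaction was positive at 1122 genes and negative at 1495, and the hap5 interaction was positive at 948 and negative at 1681. The positive share of the hap3 interaction moved from 42.87% to 47.97% after median-of-ratios scaling and 49.32% after quantile normalization, and its median over all genes from -0.058 to 0.038 and 0.057. The positive share of the hap5 interaction moved from 36.06% to 47.93% after median-of-ratios scaling and 48.74% after quantile normalization, and that scaling by ratios moved its median over all genes by 0.218.

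Direct comparison of the deletion strains gave far fewer genes. On glucose 258 genes were higher and 90 lower in the hap5 deletion than in the hap3 deletion. PDE_05049 was at 42.94, 15.58 and 38.37 FPKM and PDE_08630 at 46.06, 10.74 and 34.05 FPKM in the hap5 deletion, and both were listed at 0 in all 3 hap3 deletion libraries. PDE_09242 was at 271.97, 638.11 and 138.84 FPKM in the hap3 deletion and at 0, 15.13 and 0 FPKM in the hap5 deletion. The share of higher genes was 74.14%, and 60.88% after quantile normalization. A fit on these 6 libraries alone called 188 genes in place of 348. On bran and cellulose 24 genes were higher and 17 lower, led by PDE_02832, with a log2 change of 4.09 (SE 0.13, adjusted p = 2.58e-11), and PDE_01016, with -5.50 (SE 0.12, adjusted p = 3.16e-13). PDE_09894 was at 8.14, 20.59 and 16.69 FPKM in the hap5 deletion and 0.96, 1.32 and 6.87 FPKM in the hap3 deletion (log2 change 2.20, SE 0.47, adjusted p = 0.0235), and the change was 2.83 without hap3 deletion replicate 3, and the call was lost without hap3 deletion replicate 1 or 2 or hap5 deletion replicate 2 or 3. PDE_02833 was at 19.85 ± 2.2 FPKM in the hap3 deletion on bran and cellulose, and at 15.04 ± 6.21 FPKM on glucose, and was listed at 0 in the 12 libraries of the other strains. The count of 41 fell to 25 without hap3 deletion replicate 1 on bran and cellulose and to 24 without replicate 2. The carbon response itself, a comparison added after the data were seen, differed between the deletion strains at 408 genes, 130 with a more positive response in the hap5 deletion and 278 with a more negative one. The positive share of these moved from 31.86% to 46.52% after median-of-ratios scaling and 48.83% after quantile normalization, and the former moved the median over all genes by 0.116. Quantile normalization moved the median over all genes by -0.138 and -0.259 for the hap3 and hap5 deletions on glucose, by -0.268 and -0.171 for the carbon response of wild type and the hap3 deletion, and by -0.122 for the hap5 against the hap3 deletion on glucose. It moved the medians of the interactions by 0.115 and 0.253, and that of the difference in carbon response between deletions by 0.137.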

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

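The comparison of carbon responses between the 2 deletion strains was chosen after the data were seen. Each result here is a difference between strains in the response to the carbon source. The response to bran and cellulose differed from wild type at 2617 genes in the hap3 deletion and at 2629 genes in the hap5 deletion, and between the deletion strains at 408 genes.

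Libraries were then divided in other ways. For the hap3 interaction 3 of 100 splits of the 12 libraries, the real one included, called as many genes, with 4700 in the highest other split, and for the hap5 interaction 3 of 100, with 4314. For the comparison of carbon responses between the deletion strains 9 of 100 splits called 408 genes or more, and the highest other split called 4573. Counts above the real ones point to a structure of the samples, since random splits can set strains and carbon sources against each other. These splits therefore do not settle whether chance is excluded for any of the 3 counts.

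Other comparisons had 10 splits of 6 libraries each, too few for a share under 5%. Against wild type, the hap3 deletion gave 2088 calls on glucose with 10 in the highest other split, and 2612 on bran and cellulose with 2. For the hap5 deletion the counts were 2138 with 2, and 2571 with 1. Between carbon sources they were 3226 with 3 in wild type, 2794 with 1 in the hap3 deletion and 2159 with 2 in the hap5 deletion. Between the deletion strains they were 348 with 10 on glucose and 41 with 11 on bran and cellulose.

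The hap5 and hap3 deletion libraries differed at 348 genes on glucose and at 41 on bran and cellulose. Without replicate 2 of the hap3 deletion on glucose, the library that stood apart, 318 genes were called, which argues against that library as the whole cause. After median-of-ratios scaling 319 genes were called on glucose, which argues against scaling between libraries as the whole cause. A fit on the compared groups alone called fewer genes on glucose, and the hap3 deletion on glucose had the lowest correlation within a group (0.9526). The fit on the compared groups alone drops the shared estimate of spread, but it also has fewer libraries and fewer genes tested. It therefore does not settle whether the shared estimate raised the glucose count. Its count on bran and cellulose is not given here, so the media were not compared under that fit. A difference between the strains that depends on medium stays open as a candidate explanation, and the count on bran and cellulose itself changed with single libraries.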

How the results depend on the processing

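No count of calls changed by more than 1.5 times with a pseudocount of 0.1, no filter, a filter of 5 FPKM or either scaling. The same held without the genes listed at 0 in part of a group, an alternative chosen after the data were seen. Similar counts did not mean the same genes. Quantile normalization kept 1700 of 2088 calls for the hap3 deletion and 1541 of 2138 for the hap5 deletion against wild type on glucose. It kept 2575 of 3226 for carbon source in wild type and 2063 of 2159 in the hap5 deletion. Of the 408 calls for the difference in carbon response between deletions it kept 314. Named genes kept direction and call in 356 of 360 fits without 1 library and in 378 of 379 other alternatives; the 5 exceptions were of PDE_09894, higher in the hap5 than the hap3 deletion on bran and cellulose, whose log2 change of 2.20 kept its direction but missed the adjusted p in the fit on those groups alone, and lay at 1.83 without hap3 deletion replicate 1. Named genes were chosen in these data by the size of their change, so the rate at which they kept their call does not speak for other calls. Leaving out single libraries kept 286 of 288 counts within 1.5 times. The exceptions were for the hap5 against the hap3 deletion on bran and cellulose, where counts ran from 24 to 52 around 41, with 25 and 24 without replicates 1 and 2 of the hap3 deletion; the cause was not tested. Fitting the compared groups alone called 188 genes for the hap5 against the hap3 deletion on glucose, with fewer libraries and 8095 genes tested.

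Without a minimum fold, which by construction adds calls, counts against wild type were 5170 and 5192 on glucose and 5687 and 5622 on bran and cellulose for the hap3 and hap5 deletions. Carbon source gave 6148 genes in wild type, 6096 in the hap3 deletion and 5452 in the hap5 deletion, and the interactions 4763 and 4915. The hap5 and hap3 deletions differed at 1716 genes on glucose and 188 on bran and cellulose, and in carbon response at 1308. Genes called alike in both deletions numbered 4205 on glucose and 5148 on bran and cellulose. Of wild type genes higher on bran and cellulose, 2275 and 1814 were called alike in the hap3 and hap5 deletions and 1827 had a smaller or reversed response in both. Of those higher on glucose the counts were 1715, 1707 and 985. Genes higher in both deletions on both media numbered 1498, lower ones 688 and those opposite between media 740.

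Replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.122 to 0.202, with 1 of 45 over 0.1, and 7 of 18 libraries correlated best with their own number. A replicate block gave 350 calls for the hap5 against the hap3 deletion on glucose and moved no count by more than 1.5 times. A test for read counts and the gene list tests were not run, as the values are FPKM without gene descriptions. Depth is unknown, so the counting error of genes near the filter of 1 FPKM cannot be given.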

Other observations

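The tests of genes low in 1 strain, the counts of genes on or off and the counts of runs were chosen after the values were seen. In both deletion strains and on both media 519 genes were called higher than in wild type and 236 lower, and 149 went in opposite directions on the 2 media. At 10 FPKM or more in all 12 deletion libraries and under 1 FPKM in all 6 wild type libraries stood 6 genes, among them PDE_06665, at 101.62 to 271.58 FPKM against 0. The reverse held for 2 genes, PDE_02960, at 15.65 to 89.44 FPKM in wild type and at most 0.43 FPKM in the deletion strains, and PDE_06420, at 20.06 to 88.2 FPKM and 0. Within glucose 27 genes were on and 12 off in the deletion libraries by the same limits, and within bran and cellulose 55 and 44. By the search for genes low in 1 strain, 40 genes were at least 4 times lower in all wild type libraries than in every deletion library, with at least 2 FPKM in these. A gene lowered alike in both deletions cannot pass that search for either of them. The 40 genes are therefore not comparable with the 1 gene of each deletion strain.

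Genes with neighbouring PDE numbers changed together. Taking tag numbers as an order, 420 of 7539 adjacent pairs were called in the same direction in the hap3 deletion on glucose, against a mean of 233 in 1000 permuted orders, and 619 on bran and cellulose against 343.7. In the hap5 deletion there were 510 against 270.2 and 608 against 332.8. The lowest of these 4 ratios was 1.8, and each adjusted p over 5 comparisons was 0.001, the smallest the permutations can give. Runs of 4 or more tags called alike numbered 43 in the hap5 deletion on glucose, against 4.73 in permuted orders, and the longest, PDE_00789 to PDE_00811, held 23 genes with a median log2 change of 4.371 there and 3.886 in the hap3 deletion on bran and cellulose. The run PDE_09226 to PDE_09244 held 19 genes, with a median change of 6.144 in the hap3 deletion on glucose and 6.944 in wild type on bran and cellulose. PDE_09235, PDE_09236 and PDE_09242, named above in separate comparisons, lie within this run. Replicate 2 of the hap3 deletion was the highest of its group at each of them on both media, so they may not be independent examples.

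Reads shared by adjoining or overlapping gene models would raise the correlation of changes at tag distances of 1 and 2 only. At distance 5 the lowest correlation in the 4 deletion comparisons was 0.0565, above the upper bound of permuted orders in each, of which the highest was 0.0279, so the tables argue against shared reads as the whole cause. At distance 1 correlations were 0.163 to 0.193, so shared reads may still add to them. That genes at nearby loci respond together, as in gene clusters, stays an untested hypothesis, since the ratio of 1.8 restates the pattern. The pattern was not limited to the deletions, since 872 adjacent pairs against 554 changed alike between carbon sources in wild type.

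Among genes at 2 FPKM or more in all other libraries, the only one at least 4 times lower in all libraries of a deletion strain was PDE_02832 for hap3 and PDE_01016 for hap5. That the gene is the deleted one stays an untested hypothesis: the count of 1 per strain restates the pattern, and no table used here names either gene. The lowest correlation within a group was 0.9526 and the highest between wild type and deletion libraries 0.8741, which argues against a library mislabelled between wild type and a deletion strain. The gene of each strain with the largest gap on 1 medium, PDE_02832 or PDE_01016 in either case, put 0 libraries of the other medium out of place, which argues against a library mislabelled between the deletion strains. PDE_02832 kept 8.93 to 12.18 FPKM in the hap3 deletion, and the next tag, PDE_02833, was listed above 0 there and in no other library, which was not explained by a test.

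PDE_04423 was listed at 0 in wild type replicate 3 on bran and cellulose, beside 7327.59 and 4497.8 FPKM in replicates 1 and 2, and in hap5 deletion replicate 1 on glucose, beside 10873.28 and 8625.51 FPKM in replicates 2 and 3. It was between 4497.8 and 14137.81 FPKM in the other 16 libraries.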
